A study of Homo sapiens with 28 samples.

How the data were processed

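RNA sequencing measured the messenger RNA of Kelly cells, an established MYCN-amplified neuroblastoma line, 48 h after transfection with 25 nM of a synthetic microRNA mimic or a scrambled control. The 28 libraries fall into 7 groups of 4 by their titles: the scrambled control, the miR-99b-5p mimic, and mimics of miR-1283, miR-485-3p, miR-1915-3p, miR-380-3p and miR-100-3p. The titles of miR-1915-3p replicates 1 and 4 end in a suffix that may mark a repeat library or a repeat run, and its meaning is not stated. The labels do not say that the libraries of a group came from separate cultures, so every p-value measures the spread between these libraries.

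The authors aligned the reads to hg19 with STAR, of which the processing notes give no version. The deposited table holds expected counts per gene, of which 10.2% are not whole numbers. Neither the counting tool, the annotation nor the meaning of its filtering is stated. The table has 30887 rows, of which 951 hold no count in any library, 412 repeat a symbol and 19 are copies of pseudoautosomal genes on the Y chromosome. No column was left without a sample. Library totals ran from 10.99 M to 23.3 M expected counts, with a median of 15.0 M. Intervals for single counts were not used, since the spread between libraries sets the precision. Identifiers were compared with current gene names. Of the tested genes, 12943 carried the current symbol, 1781 carried a symbol no longer in use, 195 had an identifier absent from the reference and 139 carried the symbol of another gene. None of the 139 is in a gene list, and 1 of them is named in the text.

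Expected counts were rounded to whole numbers. Genes were kept with the default filter of edgeR 4.0.16 (filterByExpr), which left 15058. Scaling was by TMM, with factors from 0.948 to 1.03. The quasi-likelihood test of edgeR was fitted to all 28 libraries, with 21 residual degrees of freedom, a common dispersion of 0.015 and a coefficient of variation of 12.2%. Each mimic was compared with the control, and each of the 15 pairs of mimics was compared directly. All tests were two-sided. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. A 2-fold change means a log2 change of at least 1. CPM, the counts scaled by effective library size, are given as mean ± SD of 4 libraries, and log2 changes as estimate ± SE.

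Seed sites were heptamers complementary to positions 2 to 8 of the mature microRNA, with sequences taken from general knowledge. They were searched in the longest 3′ UTR of each gene in GENCODE v29 on GRCh38, with UTRs of at least 50 bases. This annotation differs from the authors' hg19, and all coordinates in the text are GRCh38. A UTR was found for 16105 genes of the table, of which 12529 were tested. The sets of genes with a site for each of the 6 mimics were tested under each of the 6 mimics (36 tests) with limma 3.58.1 (voom and camera). Camera was run with its preset correlation of 0.01 and again with an estimated correlation, and log2 CPM used a prior count of 2. All heptamers found in at least 20 genes were also ranked by their association with the log2 change, adjusted for UTR length.

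The same set test was applied to 22 gene lists under each mimic, adjusted over all lists and mimics. Those reported on were targets of MYC and MYCN, DNA replication, mitosis, double-strand break repair, the BCL2 family, anthracycline transport and metabolism, adrenergic identity, mesenchymal genes, neuronal differentiation, interferon response and cholesterol synthesis. The others were unfolded protein and amino acid stress, the PI3K and mTOR pathway, hypoxia and glycolysis, the microRNA pathway, cytosolic ribosomal proteins, the respiratory chain, the TGF-beta and BMP pathway, mitochondrially encoded mRNAs, markers of other cell types, and reported targets of the miR-99 and miR-100 family. One further list was tested and adjusted with the rest and is not described here. The lists were written from general knowledge. Each list also has a count of called members adjusted over the list alone.

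Genes named in the text follow a rule. For each mimic it takes the 8 largest rises and 8 largest falls among called genes with a mean log2 CPM of at least 2 and all 4 mimic libraries on the same side of all 4 controls. It adds the 5 called fallers with a seed site and the smallest p, up to 4 members of each list with the smallest adjusted p, and background genes including MYCN, ALK, MTOR, IGF1R, TOP2A and ABCC1. Some genes that met the rule are not described here. Groups, comparisons, lists, this rule and most alternatives were fixed before the data were examined.

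The alternatives were DESeq2 1.42.0 with its own size factors, limma-voom, median-of-ratios, upper-quartile and library-size scaling, no filter, a mean CPM of at least 5, a replicate block, runs of library codes as a covariate, only the 8 libraries of a comparison, the other 5 mimics as the reference and each library left out in turn. For seed sites they were octamers, hexamers, any annotated UTR, coding sequence, and removal of UTR length and GC content. Chosen after seeing the data were a covariate for the GC slope of each library, the same with an estimated correlation, leaving out 7 GC-deviant libraries, the ranking of heptamers with GC content, and splits of the seed sets after removal of UTR length and GC content. The GC slope is the slope of log2 CPM on the GC content of the transcripts in a library.

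The method was tested on simulated data with 14932 genes and 200 planted changes per comparison. Planted 2-fold changes were recovered in 77.6% to 91% of genes, 1.5-fold changes in 49.3% to 59.7%, and false calls made up 2.7% to 7.1% of calls. Camera recovered 6 of 6 seed sets lowered by 0.1 on the log2 scale and called 0 of 30 others. The simulated genes varied independently and without the GC trend of the real libraries. The simulation therefore does not measure how often sets are called falsely in the real libraries. Other tools were R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Reads and the small RNA content of the cells were not analysed here.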

Results

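Kelly cells, a neuroblastoma line with an amplified MYCN gene, were profiled by RNA sequencing 48 h after transfection with 25 nM of 1 of 6 microRNA mimics or a scrambled control. Each of the 7 groups has 4 libraries, and the 28 libraries held 10.99 M to 23.3 M expected counts. The labels do not state the purpose of the series. The comparisons below ask which messenger RNAs each mimic changed against the scrambled control, and whether genes with a matching seed site fell. Of 15058 genes tested, 5871 (39%) were called under at least 1 mimic and 4010 under exactly 1. Mitochondrially encoded mRNAs took 5.39% to 11.97% of the counts of a library. Libraries also differed in the GC content of the transcripts they held. The GC slope ran from -3.5 to 1.9, with group means ± SD of -0.95 ± 0.68 (control), -2.1 ± 0.97 (miR-99b-5p), -1.59 ± 1.09 (miR-380-3p), -0.65 ± 1.97 (miR-485-3p), -1.65 ± 1.49 (miR-100-3p), -1.21 ± 1.1 (miR-1915-3p) and -1.49 ± 1.43 (miR-1283).

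**Figure D1:**
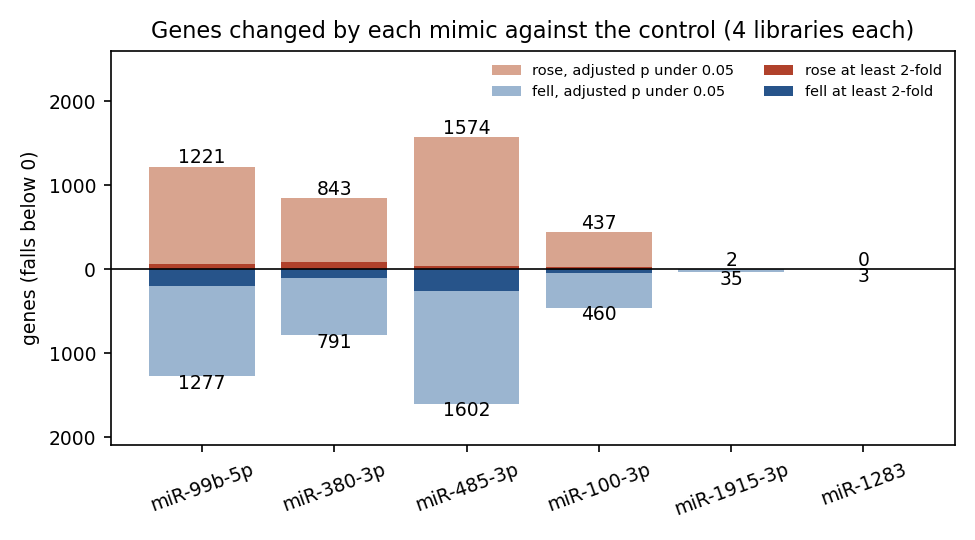
Number of genes called up or down against the scrambled control for each mimic (edgeR, adjusted p under 0.05, 4 libraries per group, 15058 genes tested). The bars range from 3176 genes in all under miR-485-3p to 3 under miR-1283.

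Under miR-99b-5p, EPAS1 (ENSG00000116016), the hypoxia-inducible factor HIF-2 alpha, fell from 756 ± 17.8 to 185 ± 58.3 CPM (n = 4, log2 change -2.03 ± 0.12, adjusted p = 3.14e-12). MTOR (ENSG00000198793), the kinase of the mTOR complexes, fell from 135 ± 10.2 to 71.2 ± 4.87 CPM (-0.93 ± 0.07, adjusted p = 7.83e-10). MYCN (ENSG00000134323), the driver oncogene of this line, fell from 5053 ± 206 to 3429 ± 227 CPM (-0.56 ± 0.08, adjusted p = 1.69e-05). DCX, a microtubule protein of migrating neurons, rose from 19.7 ± 0.171 to 63.3 ± 15.1 CPM (1.68 ± 0.16, adjusted p = 1.15e-08). In all, 1221 genes rose and 1277 fell, and of the 265 that changed at least 2-fold, 66 rose and 199 fell.

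The other large rises under miR-99b-5p were FREM1, an extracellular matrix protein (1.76 ± 0.18), PFKFB3, a regulator of glycolysis (1.66 ± 0.17), the protocadherin PCDH9 (1.48 ± 0.17), the tropomodulin TMOD1 (1.43 ± 0.10), the orphan nuclear receptor ESRRG (1.37 ± 0.16), the transcription factor BACH2 (1.36 ± 0.15) and the secretogranin SCG2 (1.31 ± 0.10). The other large falls were thyroglobulin, TG (-2.15 ± 0.16), the Wnt receptor FZD5 (-2.13 ± 0.20), HENMT1, a small RNA methyltransferase (-2.10 ± 0.20), TRIM71, a stem cell ubiquitin ligase (-2.02 ± 0.15), TPRG1L (-1.89 ± 0.10), the proton pump subunit ATP6AP1 (-1.84 ± 0.12) and WDR18 (-1.74 ± 0.32). IGF1R, a growth factor receptor, fell by less (-0.33 ± 0.09, adjusted p = 0.0126), and was not called without miR-99b-5p replicate 4 (adjusted p = 0.0603). ALK (adjusted p = 0.076), TOP2A (0.245) and ABCC1 (0.0647) were not called in the main test. ALK was called lower with the replicate block (-0.308, adjusted p = 0.00186), the GC slope as a covariate (-0.286, adjusted p = 0.029, chosen after seeing the data) and without miR-99b-5p replicate 7 (-0.377, adjusted p = 0.00605). ABCC1 was called higher with DESeq2 (adjusted p = 0.0447), the block (0.0183) and the other 5 mimics as the reference (0.00673).

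Genes with a miR-99b-5p seed site fell as a set. Of 158 such genes, 40.51% were called lower, against 8.87% of the genes without a site, and their mean log2 change was lower by -0.31 (adjusted p = 1.01e-11; adjusted p = 0.0271 with an estimated correlation). The smallest p-values among them belonged to the pseudokinase TRIB2 (-1.20 ± 0.08), TRIM71, the histone deacetylase complex member SUDS3 (-1.17 ± 0.09), the chromatin remodeller BAZ2A (-1.20 ± 0.09) and the nuclear receptor NR6A1 (-1.30 ± 0.10). The site in MTOR lies on chromosome 1 at 11107184 to 11107190 in the 3′ UTR, and BAZ2A has sites on chromosome 12 at 56597042 to 56597048 and 56597997 to 56598003. Of 13 reported targets of the miR-99 and miR-100 family, 9 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 2.7e-10; adjusted p = 0.00139 with an estimated correlation). They included the remodeller SMARCA5 (-1.34 ± 0.12) and the ubiquitin ligase adaptor KBTBD8 (-1.49 ± 0.14). Under miR-99b-5p the sets with a miR-380-3p site and a miR-1283 site were called higher (adjusted p = 0.0303 and 0.0381; adjusted p = 0.958 with an estimated correlation for both). With GC content as a term, added after seeing the data, the coefficients of their heptamers went from 0.052 to -0.006 and from 0.041 to 0.006.

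Genes of neuronal differentiation rose under miR-99b-5p. Of 27, 9 rose and 0 fell (12 and 0 adjusted over the list alone; adjusted p = 8.6e-05; adjusted p = 0.0264 with an estimated correlation), among them the tubulin binders MAPT (0.60 ± 0.07) and STMN4 (0.86 ± 0.11). Of 22 cholesterol genes, 1 rose and 12 fell (1 and 15 adjusted over the list alone; adjusted p = 0.000431; adjusted p = 0.648 with an estimated correlation). The regulator SREBF2 (-0.47 ± 0.09) and the enzyme LSS (-0.51 ± 0.11) were among them. Of 22 hypoxia and glycolysis genes, 8 rose and 1 fell (9 and 1 adjusted over the list alone; adjusted p = 0.00219; adjusted p = 0.719 with an estimated correlation), with the mitophagy receptor BNIP3 at 0.77 ± 0.07 and the kinase PDK1 at 0.60 ± 0.13. Of 27 adrenergic identity genes, 3 rose and 9 fell, including the dopamine-forming enzyme DDC (-0.83 ± 0.08), but the list was not called (adjusted p = 0.154). It was called lower with the replicate block (0.0465) and without miR-99b-5p replicate 7 (0.0419).

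Of 74 ribosomal protein genes, 3 rose and 1 fell under miR-99b-5p (1 and 0 adjusted over the list alone; adjusted p = 0.0212; adjusted p = 0.896 with an estimated correlation), with RPL4 at 0.24 ± 0.05. This call was lost without control replicate 5 (adjusted p = 0.0909) or miR-99b-5p replicate 4 (0.135). Of 51 respiratory chain genes, 0 rose and 5 fell (0 and 4 adjusted over the list alone; adjusted p = 0.0191; adjusted p = 0.785 with an estimated correlation), including the complex I subunit NDUFB5 (-0.54 ± 0.08). That call was lost without control replicate 4 (0.0532) or miR-99b-5p replicate 7 (0.252). Of 6 markers of other cell types, 3 fell (0 rose and 3 fell adjusted over the list alone; adjusted p = 0.0404; adjusted p = 0.378 with an estimated correlation). They were the endothelial VWF (-1.44 ± 0.23), the collagen COL1A1 (-0.99 ± 0.18) and the keratin KRT19 (-0.71 ± 0.22). Without control replicate 5 the list (0.068) and KRT19 (0.135) were not called. KRT19 was also not called without control replicate 4 (0.0517) or miR-99b-5p replicate 3 (0.0644), 4 (0.0649) or 7 (0.0535).

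**Figure D2:**
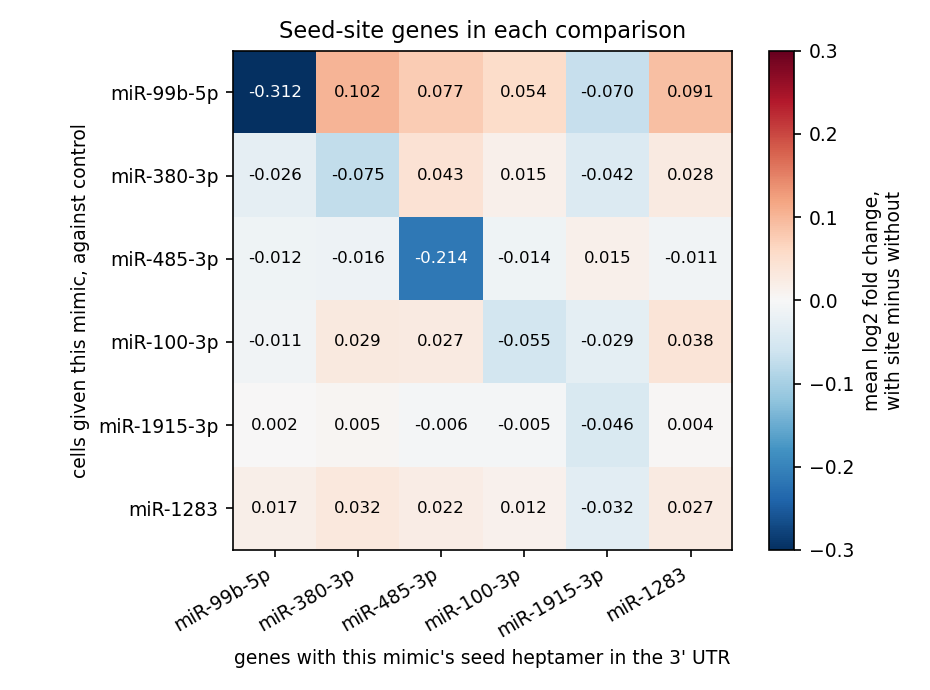
Mean log2 change of genes with a seed site minus genes without one, for the seed of each mimic (columns) under each mimic (12529 genes with a 3′ UTR). On the diagonal the differences run from -0.31 (miR-99b-5p) to 0.03 (miR-1283).

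Under miR-380-3p, IGF2 (ENSG00000167244), a growth factor, fell from 4914 ± 304 to 1339 ± 301 CPM (n = 4, log2 change -1.88 ± 0.17, adjusted p = 3.13e-08). The TGF-beta receptor TGFBR1 fell from 30.1 ± 2.91 to 10.0 ± 2.85 CPM (-1.60 ± 0.18, adjusted p = 1.03e-06). The intermediate filament VIM rose from 47.6 ± 9.64 to 138 ± 10.6 CPM (1.54 ± 0.14, adjusted p = 1.27e-08), and the neuronal stathmin STMN2 rose from 222 ± 9.72 to 502 ± 94.5 CPM (1.18 ± 0.11, adjusted p = 1.95e-08). MYCN fell from 5053 ± 206 to 4050 ± 360 CPM (-0.32 ± 0.08, adjusted p = 0.0104). In all, 843 genes rose and 791 fell, and of 192 that changed at least 2-fold, 87 rose and 105 fell. Without miR-380-3p replicate 3 the number called was 1056 against 1634.

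Other large rises under miR-380-3p were the ion channels KCNB2 (1.22 ± 0.18) and SCN9A (1.19 ± 0.21), the exchange factor ARHGEF28 (1.17 ± 0.15), the axon guidance ligand SLIT2 (1.14 ± 0.14), somatostatin, SST (1.12 ± 0.24), and the nuclear protein TOX (1.08 ± 0.15). Other large falls were PPIL3 (-1.69 ± 0.14), the flippase subunit TMEM30A (-1.66 ± 0.15), the vesicle GTPase RAB21 (-1.65 ± 0.12), the protocadherin PCDH19 (-1.60 ± 0.14), the muscarinic receptor CHRM1 (-1.53 ± 0.23) and the entry labelled RBM4B, whose identifier is that of STK26 (-1.70 ± 0.15). IGF1R fell (-0.46 ± 0.09, adjusted p = 0.0013), and ALK (adjusted p = 0.113), MTOR (0.24), TOP2A (0.104) and ABCC1 (0.0523) were not called in the main test. ABCC1 was called lower with DESeq2 (adjusted p = 0.0278), the block (0.035), the GC slope (0.0125) and the other 5 mimics as the reference (0.000394), and without the GC-deviant libraries (0.0337), control replicate 4 (0.0256) or miR-380-3p replicate 1 (0.0276). ALK was called lower with the block (0.0495) and the GC slope (0.0477), and TOP2A higher with the GC slope (0.0391) and without the GC-deviant libraries (0.0328).

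Among 1885 genes with a miR-380-3p seed site, 14.59% were called lower, against 4.13% of the others, with a mean difference of -0.075 (adjusted p = 0.0239; adjusted p = 0.958 with an estimated correlation). The set was not called without control replicate 1 (-0.053, adjusted p = 0.0638) or miR-380-3p replicate 2 (-0.028, adjusted p = 0.334). It was also not called lower with the replicate block, without the GC-deviant libraries, or with hexamers or coding sequence sites. The ubiquitin ligase UBR7 (-1.24 ± 0.07), the modifier SUMO2 (-1.03 ± 0.08) and the chaperone DNAJA2 (-0.85 ± 0.07) were among those with the smallest p-values. IGF2 has a site on chromosome 11 at 2130678 to 2130684, and TGFBR1 has 4 on chromosome 9, starting at 99149913, 99150429, 99151166 and 99153634.

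Neuronal differentiation genes also rose under miR-380-3p. Of 27, 9 rose and 1 fell (12 and 3 adjusted over the list alone; adjusted p = 0.0047; adjusted p = 0.141 with an estimated correlation), including the neurofilaments NEFL (0.71 ± 0.06) and NEFM (0.65 ± 0.08). Of 22 hypoxia and glycolysis genes, 0 rose and 7 fell (0 and 8 adjusted over the list alone; adjusted p = 0.000107; adjusted p = 0.594 with an estimated correlation), including PDK1 (-1.19 ± 0.13) and the angiogenic factor VEGFA (-0.53 ± 0.07). Of 27 adrenergic identity genes, 1 rose and 8 fell (2 and 10 adjusted over the list alone; adjusted p = 0.0141; adjusted p = 0.736 with an estimated correlation), including DDC (-0.81 ± 0.08) and the monoamine transporter SLC18A2 (-0.83 ± 0.13). That call was lost without miR-380-3p replicate 1 (0.0594), and with the other 5 mimics as the reference both the adrenergic (0.282) and the neuronal call (0.147) were lost.

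Of 51 respiratory chain genes, 0 rose and 2 fell under miR-380-3p (0 and 1 adjusted over the list alone; adjusted p = 0.0047; adjusted p = 0.736 with an estimated correlation), of which COX7B stood at -0.31 ± 0.07. The mitosis list was called higher, with 0 of 32 members up and 1 down (0 and 1 adjusted over the list alone; adjusted p = 0.0355; adjusted p = 0.736 with an estimated correlation). The member that fell was the phosphatase CDC25B (-0.30 ± 0.08), which was lost without control replicate 4 (0.0795) or miR-380-3p replicate 3 (0.0773) or 4 (0.0573). The list was lost without control replicate 1 (0.0635), 2 (0.0511) or 5 (0.0567) or miR-380-3p replicate 2 (0.0668) or 4 (0.0661). Of 13 reported miR-99 and miR-100 targets, 0 rose and 2 fell (0 and 3 adjusted over the list alone; adjusted p = 0.0264; adjusted p = 0.405 with an estimated correlation), IGF1R being the clearest, and the call was lost without control replicate 5 (0.0909). The apoptosis inhibitor BCL2 (-0.996 ± 0.13) and the signal transducer SMAD5 (-0.97 ± 0.13) fell in lists that were not called.

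Under miR-485-3p, NRAS (ENSG00000213281), a GTPase of growth signalling, fell from 226 ± 14.4 to 51.0 ± 14.4 CPM (n = 4, log2 change -2.15 ± 0.13, adjusted p = 2.18e-12). The GTPase RHOQ fell from 52.96 ± 1.86 to 11.3 ± 2.01 CPM (-2.24 ± 0.11, adjusted p = 4.48e-14), and the MYC-binding protein MYCBP fell from 29.2 ± 2.64 to 6.57 ± 1.56 CPM (-2.16 ± 0.12, adjusted p = 8.23e-13). The actin-like ACTL8 rose from 4.76 ± 0.446 to 25.0 ± 3.53 CPM (2.40 ± 0.18, adjusted p = 1.5e-10). In all, 1574 genes rose and 1602 fell, and of 302 that changed at least 2-fold, 36 rose and 266 fell. MYCN was at -0.22 ± 0.08 (adjusted p = 0.061), and was called with DESeq2 (0.036), library-size scaling (0.0378) and the GC slope (0.00889), and without the GC-deviant libraries (0.0178) or miR-485-3p replicate 2 (0.0331) or 5 (0.0293).

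Other large rises under miR-485-3p were the pseudogene ADCY10P1 (1.36 ± 0.14), PHTF2 (1.22 ± 0.13), the tight junction protein CGN (1.17 ± 0.08), TPBGL (1.11 ± 0.19), the adenosine receptor ADORA1 (1.09 ± 0.15), NR6A1 (1.09 ± 0.10) and the metalloprotease MMP11 (1.01 ± 0.25). Other large falls were CHRM1 (-2.07 ± 0.24), the RNA-binding protein NANOS1 (-1.89 ± 0.14), TMEM119 (-1.79 ± 0.12) and the microRNA host gene MIR17HG (-1.78 ± 0.17). The vesicle protein VAMP7 (-1.97 ± 0.12) is pseudoautosomal, and the split of its reads between copies is uncertain. ALK (adjusted p = 0.397), MTOR (0.995), IGF1R (0.283), TOP2A (0.226) and ABCC1 (0.43) were not called in the main test. TOP2A was called higher with the GC slope (adjusted p = 0.0311) and without the GC-deviant libraries (0.0192) or miR-485-3p replicate 2 (0.00974). With the block ALK (0.0457) and IGF1R (0.0417) were called lower, and with the other 5 mimics as the reference MTOR was called higher (0.00642).

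Among 1786 genes with a miR-485-3p seed site, 28% were called lower, against 8.2% of the others, with a mean difference of -0.21 (adjusted p = 1.44e-11; adjusted p = 0.958 with an estimated correlation). The smallest p-values among them belonged to the proline-synthesis enzyme ALDH18A1 (-1.47 ± 0.06) and RHOQ, and the tetraspanin TSPAN3 (-1.04 ± 0.05) followed. NRAS has sites on chromosome 1 at 114704740 to 114704746 and 114707283 to 114707289, both followed by A.

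Cholesterol genes rose under miR-485-3p. Of 22, 13 rose and 0 fell (14 and 1 adjusted over the list alone; adjusted p = 0.000609; adjusted p = 0.648 with an estimated correlation), including the enzymes DHCR7 (0.69 ± 0.12) and MSMO1 (0.78 ± 0.15). Of 37 DNA replication genes, 15 rose and 3 fell (18 and 3 adjusted over the list alone; adjusted p = 0.00302; adjusted p = 0.5 with an estimated correlation). The ribonucleotide reductase subunit RRM2 (0.54 ± 0.06) and cyclin E1, CCNE1 (0.70 ± 0.10), rose, while thymidylate synthase, TYMS (-0.92 ± 0.07), and the chromatin assembly factor CHAF1A (-0.60 ± 0.07) fell. Of 27 adrenergic identity genes, 0 rose and 10 fell (2 and 12 adjusted over the list alone; adjusted p = 0.00245; adjusted p = 0.648 with an estimated correlation), including the granin CHGA (-0.84 ± 0.12) and the transcription factor TFAP2B (-0.81 ± 0.14). With the other 5 mimics as the reference the adrenergic call was lost (adjusted p = 0.0678). Of 13 mesenchymal genes, 1 rose and 7 fell (2 and 8 adjusted over the list alone; adjusted p = 0.00365; adjusted p = 0.141 with an estimated correlation). The receptors NOTCH2 (-3.09 ± 0.40) and NOTCH3 (-1.46 ± 0.24) and the annexin ANXA2 (-0.96 ± 0.11) fell, and the adhesion receptor CD44 rose (0.92 ± 0.15). With a mean CPM of at least 5, which leaves out NOTCH2 (1.405 ± 0.152 CPM in the control), the mean of the mesenchymal list went from -0.77 to -0.337 and it was not called (adjusted p = 0.11).

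**Figure D3:**
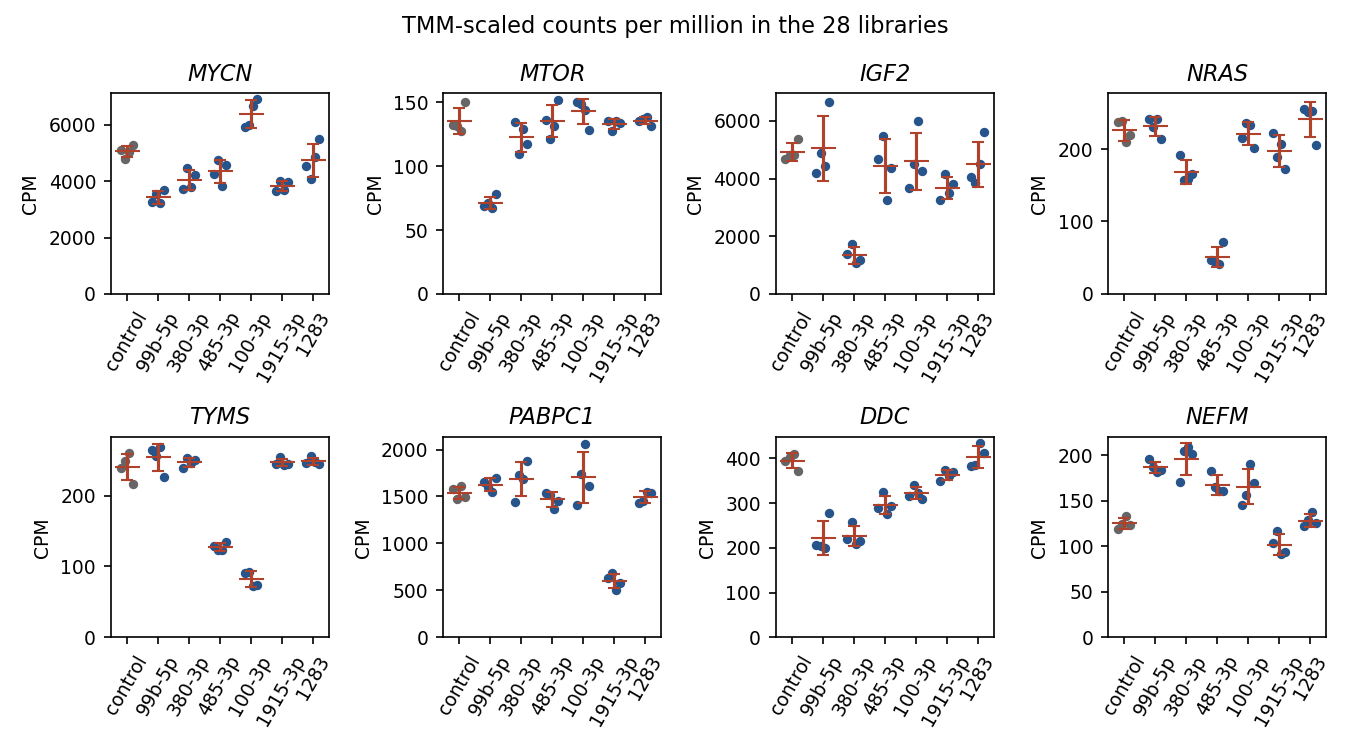
CPM of 8 genes in each of the 28 libraries, by group, with the mean and SD of 4 libraries. NRAS sits at 51.0 ± 14.4 CPM under miR-485-3p against 226 ± 14.4 in the control, and TYMS at 82.1 ± 11 under miR-100-3p against 241 ± 18.4.

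Under miR-100-3p, TYMS (ENSG00000176890), the enzyme that makes thymidylate for DNA, fell from 241 ± 18.4 to 82.1 ± 11 CPM (n = 4, log2 change -1.55 ± 0.07, adjusted p = 8.46e-14). The vesicle protein VAMP3 fell from 74.2 ± 5.44 to 25.1 ± 2 CPM, the kinase RPS6KA2 fell to 14.4 ± 2.35 from 41.1 ± 2.37 CPM (-1.52 ± 0.10, adjusted p = 2.88e-11), and SKP2, the ubiquitin ligase subunit that targets p27, fell from 162 ± 8.75 to 70.8 ± 7.66 CPM (-1.19 ± 0.09, adjusted p = 5.49e-10). MYCN rose from 5053 ± 206 to 6380 ± 496 CPM (0.34 ± 0.08, adjusted p = 0.0123). The sphingolipid receptor S1PR1 (1.52 ± 0.21) and CD44 (1.36 ± 0.15) had the largest rises of the named genes. In all, 437 genes rose and 460 fell, and of 77 that changed at least 2-fold, 28 rose and 49 fell. Of the libraries, leaving out miR-100-3p replicate 3 gave 551 called genes and 48 at 2-fold, control replicate 2 gave 575 called genes and control replicate 5 gave 597.

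Other large rises under miR-100-3p were the nuclear receptor NR4A3 (1.29 ± 0.16), the matrix protein TNR (1.22 ± 0.18), the serpin SERPINB9 (1.17 ± 0.15), SLIT2 (1.15 ± 0.14), FZD5 (1.09 ± 0.18) and the secreted STC1 (1.04 ± 0.20). Other large falls were CNRIP1 (-1.48 ± 0.09), the repressor of neuronal genes REST (-1.31 ± 0.19), the phosphatase PTPN14 (-1.28 ± 0.23) and the sulfotransferase SULT1C4 (-1.12 ± 0.15). ALK (adjusted p = 0.447), MTOR (0.625), IGF1R (0.651), TOP2A (0.977) and ABCC1 (0.609) were not called, except MTOR with the other 5 mimics as the reference (0.296, adjusted p = 0.000375).

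Among 1313 genes with a miR-100-3p seed site, 9.44% were called lower, against 2.75% of the others, with a mean difference of -0.055 (adjusted p = 0.0239; adjusted p = 0.958 with an estimated correlation). The set was not called without miR-100-3p replicate 4 (-0.016, adjusted p = 0.26). The call was also lost with the replicate block, without the GC-deviant libraries, and with hexamers or coding sequence sites. VAMP3 has a site on chromosome 1 at 7779719 to 7779725 and SKP2 on chromosome 5 at 36182359 to 36182365, both followed by A. The membrane-bending protein PACSIN2 (-0.63 ± 0.06) was also among those with the smallest p-values. TYMS has 0 such sites in its 3′ UTR.

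Interferon response genes fell under miR-100-3p. Of 11, 0 rose and 4 fell (0 and 4 adjusted over the list alone; adjusted p = 0.00126; adjusted p = 0.0264 with an estimated correlation). They were IFIT1 (-1.59 ± 0.24), OAS1 (-1.11 ± 0.17), OAS3 (-0.92 ± 0.16) and IFI6 (-1.02 ± 0.25), all induced by interferon, and IFI6 was not called without miR-100-3p replicate 1 (adjusted p = 0.0502). Of 37 DNA replication genes, 0 rose and 10 fell (1 and 12 adjusted over the list alone; adjusted p = 3.97e-07; adjusted p = 0.0652 with an estimated correlation), including the ligase LIG1 (-0.35 ± 0.07). Of 27 adrenergic identity genes, 1 rose and 7 fell (2 and 9 adjusted over the list alone; adjusted p = 0.0404; adjusted p = 0.736 with an estimated correlation). The receptor RET (-0.68 ± 0.10) fell. The adrenergic call was lost without control replicate 4 (0.088) or 5 (0.0585) or miR-100-3p replicate 1 (0.146) or 2 (0.0721), and with the other 5 mimics as the reference (0.903). The miR-100-3p seed differs from that of miR-99b-5p. Of 13 reported targets of the miR-99 and miR-100 family, 0 rose and 0 fell under miR-100-3p (mean 0.017, adjusted p = 0.753). That list was called higher only against the other 5 mimics, which include miR-99b-5p (0.264, adjusted p = 0.00126).

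Under miR-1915-3p, PABPC1 (ENSG00000070756), which binds the poly(A) tail of mRNAs, fell from 1538 ± 65.9 to 598 ± 76.8 CPM (n = 4, log2 change -1.36 ± 0.09, adjusted p = 7.29e-10). SET, a histone chaperone, fell from 607 ± 16.2 to 392 ± 40.5 CPM (-0.63 ± 0.06, adjusted p = 7.67e-07), and the vitamin B12 carrier TCN2 fell from 8.55 ± 0.619 to 4.19 ± 0.548 CPM (-1.02 ± 0.12, adjusted p = 1.24e-05). The called genes numbered 37, of which 2 rose, CA5B, a mitochondrial carbonic anhydrase (0.70 ± 0.12, adjusted p = 0.00228), and AMMECR1 (0.53 ± 0.08, adjusted p = 0.00055). The other large falls were the neuronal kinase BRSK2 (-1.60 ± 0.23), GOLGA7 (-0.93 ± 0.09), PLD6 (-0.90 ± 0.08), TMEM80 (-0.89 ± 0.14), the transcription factor DEAF1 (-0.76 ± 0.13) and TUNAR (-0.74 ± 0.10). BRSK2, PABPC1 and TCN2 were the 3 genes that fell at least 2-fold. The number called was 20 without control replicate 5, 20 without miR-1915-3p replicate 3, 21 without replicate 4 and 24 without control replicate 2, and 6 genes changed 2-fold without miR-1915-3p replicate 2. DESeq2 called 86.

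MYCN fell from 5053 ± 206 to 3835 ± 188 CPM under miR-1915-3p (-0.40 ± 0.08, adjusted p = 0.0245). It was not called without control replicate 1 (adjusted p = 0.0782), 4 (0.0619) or 5 (0.106), or without miR-1915-3p replicate 1 (0.104), 3 (0.117) or 4 (0.0633). ALK (adjusted p = 0.0608), MTOR (0.999), IGF1R (0.999), TOP2A (0.999) and ABCC1 (0.999) were not called in the main test. ALK was called lower with DESeq2 (-0.433, adjusted p = 0.00535), the replicate block (-0.364, adjusted p = 0.00303), the GC slope (-0.441, adjusted p = 0.0112) and without the GC-deviant libraries (-0.488, adjusted p = 0.0433).

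Among 2893 genes with a miR-1915-3p seed site, 0.48% were called lower, against 0.22% of the others, with a mean difference of -0.046 (adjusted p = 0.00678; adjusted p = 0.958 with an estimated correlation). The set was not called without control replicate 4 (-0.032, adjusted p = 0.107) or miR-1915-3p replicate 1 (-0.029, adjusted p = 0.0973). Further alternatives under which it was not called are given with the dependence on processing. SET has a site on chromosome 9 at 128694714 to 128694720, TCN2 has a pair on chromosome 22 starting at 30626646 and 30626724, and MYCN has 1 on chromosome 2 at 15946481 to 15946487. DEAF1 and TUNAR also have sites, but none was found for PABPC1, BRSK2, GOLGA7, PLD6 or TMEM80. FAM35A (-0.65 ± 0.09) and the ribosome biogenesis factor URB2 (-0.64 ± 0.10) were also among those with the smallest p-values.

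Of the gene lists, ribosomal protein genes were called higher under miR-1915-3p with 0 of 74 members called (0 and 0 adjusted over the list alone; adjusted p = 0.0047; adjusted p = 0.838 with an estimated correlation). The respiratory chain list was called higher while 1 of 51 members, the complex I subunit NDUFA10, fell (0 up and 1 down adjusted over the list alone; adjusted p = 0.00998; adjusted p = 0.764 with an estimated correlation). Without control replicate 5 both calls were lost (adjusted p = 0.0847 and 0.0714). The ribosomal call was also lost without miR-1915-3p replicate 2 (0.09) or 4 (0.273), and the respiratory call without replicate 2 (0.196). NDUFA10 (-0.30 ± 0.06, adjusted p = 0.0254) was not called without control replicate 1 (0.0947), 2 (0.093), 4 (0.0529) or 5 (0.0852) or miR-1915-3p replicate 1 (0.114), 3 (0.142) or 4 (0.0637).

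Under miR-1283, 3 genes were called and all fell. CLCN4 (ENSG00000073464), a chloride and proton exchanger, fell from 16.4 ± 1.43 to 10.0 ± 1.68 CPM (n = 4, log2 change -0.71 ± 0.11, adjusted p = 0.0125). The myelin protein PMP22 fell from 25.4 ± 0.569 to 18.9 ± 1.32 CPM (-0.43 ± 0.07, adjusted p = 0.0125), and the arginine-synthesis enzyme ASS1 fell from 171 ± 10.8 to 132 ± 6.83 CPM (-0.38 ± 0.06, adjusted p = 0.0159). ASS1 was also called lower under miR-99b-5p, miR-380-3p, miR-100-3p and miR-1915-3p, against the same control libraries. With the other 5 mimics as the reference it did not differ under miR-1283 (0.053, adjusted p = 0.798), so its fall is not particular to this mimic. MYCN, ALK, MTOR, IGF1R, TOP2A and ABCC1 were not called (adjusted p = 1 for each). With edgeR 0 genes rose, 0 changed at least 2-fold and 453 had an unadjusted p under 0.05, while DESeq2 called 4 and limma-voom 3. The number called was 0 without control replicate 2 or 5 or miR-1283 replicate 1, 3 or 4. The adjusted p of CLCN4 was then 0.0669, 0.0619, 0.0606, 0.0704 and 0.151, that of PMP22 0.0669, 0.0619, 0.0606, 0.0544 and 0.151, and that of ASS1 0.0669, 0.17, 0.0606, 0.0544 and 0.273. PMP22 was also lost without control replicate 4 (0.0592), and ASS1 without control replicate 1 (0.119) or miR-1283 replicate 2 (0.174).

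CLCN4 has a miR-1283 site on chromosome X at 10236765 to 10236771, followed by A. The set of 2604 genes with a site was not called (mean difference 0.03, adjusted p = 0.341), with 0.04% called lower against 0.02% of the others. Without miR-1283 replicate 4 it was called higher (0.081, adjusted p = 0.000523). Interferon response genes were called lower with 0 of 11 members called (0 up and 3 down adjusted over the list alone; adjusted p = 0.00219; adjusted p = 0.0264 with an estimated correlation), with IFIT1 at -0.77 ± 0.21, OAS1 at -0.52 ± 0.16 and IFI6 at -0.78 ± 0.24. Hypoxia and glycolysis genes (adjusted p = 0.000107; adjusted p = 0.594 with an estimated correlation), cholesterol genes (adjusted p = 0.0047; adjusted p = 0.736 with an estimated correlation) and mitosis genes (adjusted p = 0.0063; adjusted p = 0.679 with an estimated correlation) were called higher. Mitochondrially encoded mRNAs were called lower (adjusted p = 0.0132; adjusted p = 0.774 with an estimated correlation). In these 4 lists 0 members were called, also adjusted over the list alone. The hypoxia call was lost without control replicate 5 (0.0534), the cholesterol call without control replicate 1 (0.0652) or miR-1283 replicate 4 (0.0643), the mitosis call without miR-1283 replicate 3 (0.175), and the mitochondrial call without control replicate 4 (0.0687) or miR-1283 replicate 1 (0.153).

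The remaining 8 lists were called under none of the 6 mimics in the main test, though single members changed. Some were called under alternatives: stress genes under miR-100-3p with the block (adjusted p = 0.0421), the GC slope (0.0361) and the other 5 mimics as the reference (0.0431), and repair genes there with the GC slope (0.00265) and that reference (0.0216). With the block repair (0.0414) and microRNA pathway (0.0173) genes were called under miR-1283. Without the GC-deviant libraries stress genes were called under miR-380-3p (0.0152) and repair genes under miR-1283 (0.0171), and some lists were called with 1 library left out. Under miR-99b-5p, 5 TGF-beta and BMP genes rose and 2 fell of 25 (7 and 2 adjusted over the list alone; adjusted p = 0.0876, and 0.0414 with the block, 0.0154 with the other 5 mimics as the reference and 0.0419 without replicate 7), including the receptors BMPR1B (0.91 ± 0.16) and ACVR2B (-0.78 ± 0.13). Of 26 stress genes of the unfolded protein response and amino acid supply, 1 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.293), including the chaperone HSPA5 (-0.82 ± 0.13). Of 27 microRNA pathway genes, 5 rose and 4 fell (6 and 4 adjusted over the list alone; adjusted p = 0.511), with the silencing factor TNRC6A at 0.69 ± 0.07 and the let-7 regulator LIN28B at -0.73 ± 0.13. Of 23 PI3K and mTOR genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone; adjusted p = 0.792). Under miR-485-3p, 6 double-strand break repair genes rose and 5 fell of 40 (8 and 5 adjusted over the list alone; adjusted p = 0.646), including the ubiquitin ligase RNF8 (-0.54 ± 0.07). There 3 of 30 MYC and MYCN targets rose and 1 fell (3 and 1 adjusted over the list alone; adjusted p = 0.283), the latter prothymosin, PTMA (-0.75 ± 0.08). Under miR-380-3p, 2 of 16 BCL2 family genes rose and 2 fell (2 and 2 adjusted over the list alone; adjusted p = 0.456). There 1 of 16 anthracycline genes rose, the drug exporter ABCB1 (0.52 ± 0.12), and 0 fell (1 and 1 adjusted over the list alone; adjusted p = 0.511).

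Compared directly, the mimics differed from each other in many genes. The largest number was 5043, between miR-99b-5p and miR-485-3p, followed by 4367 between miR-380-3p and miR-485-3p and 4298 between miR-485-3p and miR-100-3p. Between miR-99b-5p and miR-380-3p there were 3608, between miR-99b-5p and miR-100-3p 3528, and between miR-380-3p and miR-100-3p 2617. Against miR-1915-3p the numbers were 2882 (miR-99b-5p), 2190 (miR-380-3p), 3481 (miR-485-3p) and 1721 (miR-100-3p). Against miR-1283 they were 2298, 1744, 2931 and 873 in the same order, and miR-1915-3p and miR-1283 differed in 38. Across genes, which are not independent replicates, the log2 changes of the 15 pairs of mimics had r from 0.16 to 0.52, with the 4 control libraries shared. Simulated groups with no effect and shared controls gave a mean r of 0.5 (95% of draws from 0.19 to 0.76). Effects particular to a mimic lower r and are absent from these draws. The observed values therefore neither show nor exclude similar responses. With the controls split so that none was shared, the mean r of a pair ran from -0.08 (miR-100-3p and miR-1915-3p) to 0.12 (miR-380-3p and miR-100-3p).

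The share of genes in which all 4 mimic libraries lay on 1 side of all 4 controls, for which chance gives 2.86%, was 23.9% for miR-99b-5p, 17.4% for miR-380-3p, 20.2% for miR-485-3p, 12.3% for miR-100-3p, 6.63% for miR-1915-3p and 3.07% for miR-1283. Ranked by their association with a fall among 16383 heptamers, with UTR length as a term, the own seed stood at 6 for miR-99b-5p, 1 for miR-380-3p, 2 for miR-485-3p, 2 for miR-100-3p, 1 for miR-1915-3p and 14361 for miR-1283. Under miR-99b-5p rank 1 was the miR-1915-3p heptamer, which moved to 122 when GC content was added as a term after seeing the data, and the miR-99b-5p heptamer then ranked 1. With UTR length alone the miR-1915-3p heptamer ranked 32 under miR-380-3p, 16165 under miR-485-3p, 52 under miR-100-3p and 15 under miR-1283. With GC content it ranked 12733, 15573, 15286 and 2153 in the same order. Of the 30 list calls, those that hold with an estimated correlation are neuronal genes and miR-99 and miR-100 targets under miR-99b-5p, and interferon genes under miR-100-3p and miR-1283. Of these, the interferon calls were lost with a mean CPM of at least 5 (adjusted p = 0.11 and 0.265), and that of miR-1283 also with the other 5 mimics as the reference (0.279). That CPM limit also ended calls of ribosomal genes (0.11) and markers of other cell types (0.265) under miR-99b-5p, mitosis genes (0.0563) and miR-99 and miR-100 targets (0.144) under miR-380-3p and adrenergic genes under miR-100-3p (0.0991). The GC slope ended those of respiratory genes (0.113) and markers of other cell types (0.109) under miR-99b-5p, mitosis genes under miR-380-3p (0.0606), adrenergic genes under miR-100-3p (0.0932) and mitochondrially encoded mRNAs under miR-1283 (0.0651, and 0.0981 without the GC-deviant libraries, both alternatives chosen after seeing the data). The block ended those of ribosomal (0.117) and respiratory (0.136) genes under miR-99b-5p, ribosomal genes under miR-1915-3p (0.104) and cholesterol genes under miR-1283 (0.321). With the GC slope as a covariate, chosen after seeing the data, 2799 genes were called under miR-380-3p, 4884 under miR-485-3p, 1824 under miR-100-3p and 183 under miR-1915-3p.

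**Figure D4:**
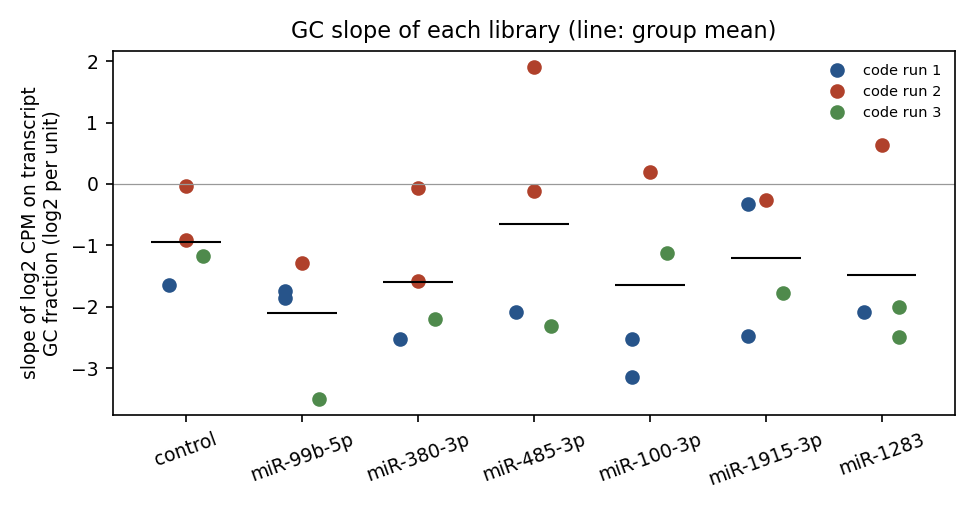
Slope of log2 CPM on transcript GC content for each of the 28 libraries, by group, coloured by the run of library codes. Slopes range from -3.5 to 1.9 and vary within every group.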

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

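All values in this part come from a search chosen before the results were seen, except that the GC slope itself was added after seeing the data. The search covered 153 groups of 4 libraries and looked for a library whose gap to the nearest of the others took up most of the range of its group. It found 7, which is no more than the about 5% of groups that chance alone gives. No biological explanation was tested for them, since no label separates the libraries of a group.

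Under miR-99b-5p, the nuclear receptor ESRRG stood at 35.9 CPM in replicate 7, against 52.3 to 54.8 in the others. Under miR-380-3p, the sodium channel SCN9A stood at 8.67 CPM in replicate 2, against 13.9 to 15. Under the same mimic, somatostatin, SST, stood at 25 CPM in replicate 1, against 41.1 to 44.1. Under miR-1915-3p, the carbonic anhydrase CA5B stood at 9.56 CPM in replicate 2, against 11.3 to 11.7. There the vitamin B12 carrier TCN2 stood at 3.38 CPM in replicate 3, against 4.4 to 4.56. There also the ribosome biogenesis factor URB2 stood at 67.5 CPM in replicate 1, against 54.2 to 56.3. The GC slope of miR-1283 replicate 4 was 0.63, against -2.5 to -2 in the other 3 libraries of that mimic.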

How the results depend on the processing

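The GC slope as a covariate, the same with an estimated correlation, and leaving out the most GC-deviant library of each group were chosen after seeing the data, and the other alternatives before. All 6 counts of called genes stayed within 1.5-fold with TMM replaced by median-of-ratios, upper-quartile or library-size scaling, with limma-voom, with a mean CPM of at least 5 and with a replicate block. The cause was not tested for any value below unless it is given. Under upper-quartile scaling 39.1% of the genes called under miR-485-3p rose, against 49.6%.

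Among counts, DESeq2 called 86 genes under miR-1915-3p, 6 of them 2-fold. With no filter 564 genes were called under miR-100-3p and 1 under miR-1283. A mean CPM of at least 5, which tests fewer genes, left 98 (miR-99b-5p), 66 (miR-380-3p), 119 (miR-485-3p) and 28 (miR-100-3p) genes changed 2-fold. The block by replicate number gave 5 genes changed 2-fold under miR-1915-3p, and the code runs gave 58 called and 5 at 2-fold. The replicate numbers were not taken to pair the libraries, since no label says so and 50.7% of the 67 pairs of libraries that share a number had residuals with an r across genes over 0.1. The mean r of those pairs was 0.111 (range -0.608 to 0.833), against -0.027 for libraries with different numbers. With only the 8 libraries of a comparison, hence fewer samples, the counts were 2000 (miR-485-3p), 491 with 46 at 2-fold (miR-100-3p), 5 at 2-fold (miR-1915-3p) and 0 (miR-1283). The GC slope gave 2799 (miR-380-3p), 4884 (miR-485-3p), 1824 (miR-100-3p) and 183 with 8 at 2-fold (miR-1915-3p). Without the GC-deviant libraries edgeR called 0 under miR-1283.

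The mean of the other 5 mimics as the reference (20 libraries, not 4) carries their effects. It gave 4200, 3149, 5158, 2578, 1072 and 253 called genes in the order of the report. At 2-fold it gave 31 under miR-1915-3p and 6 under miR-1283. Reversed against those mimics were BCL2 under miR-99b-5p (0.032), MTOR under miR-485-3p (0.201) and ASS1 under miR-1283 (0.053). So were adrenergic genes (0.13 and 0.116) and miR-99 and miR-100 targets (0.153 and 0.179) under miR-1915-3p and miR-1283. The median r of the 15 pairs of mimics was 0.27, and 0.06 with the controls split. This reference gave -0.23, but it makes r negative on average by construction and cannot test similarity. Simulated groups with no effect and shared controls gave a mean covariance of 0.0262 (0.0088 to 0.0608). The observed median was 0.0247 (0.0055 with the controls split), which the shared controls alone can give. Ribosomal genes under miR-1283 ran from -0.049 to 0.033 over the libraries left out, and reversed without its replicate 2.

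Among seed sets, that of miR-99b-5p kept its fall and its call under every alternative run. The block gave -0.059 (adjusted p = 0.0675) for miR-380-3p, -0.043 (0.0654) for miR-100-3p and 0.042 (0.0203) for miR-1283. For miR-99b-5p hexamers gave -0.176 (5.48e-07) and sites in coding sequence -0.152 (8.3e-06), and for miR-485-3p sites in coding sequence gave -0.104 (0.00496), all falls smaller by over 1.5-fold. Hexamers gave 0.004, -0.011 and -0.027 for miR-380-3p, miR-100-3p and miR-1915-3p, and sites in coding sequence gave 0.003, -0.021 and -0.028. For miR-1915-3p removal of UTR length and GC content gave -0.027 (0.173), and the other mimics as reference -0.014. An estimated correlation ended the calls of miR-380-3p (-0.075), miR-485-3p (-0.214), miR-100-3p (-0.055) and miR-1915-3p (-0.046), each at an adjusted p of 0.958, by widening the error, since the means are the same. With the GC slope and the preset correlation all 4 stayed called, at -0.132 (2.45e-06), -0.195 (4.24e-10), -0.084 (0.000698) and -0.033 (0.0324). With an estimated correlation as well they were not called (0.339, 0.118, 0.408 and 0.996). Other falls grew over 1.5-fold and stayed called: octamers gave -0.164 (4.09e-08) for miR-380-3p and -0.133 (5.59e-07) for miR-100-3p, and removal of UTR length and GC content gave -0.124 (2.26e-06) and -0.084 (0.000286). Without the GC-deviant libraries the falls of miR-380-3p (-0.064, 0.106), miR-100-3p (-0.036, 0.12) and miR-1915-3p (-0.015, 0.433) were not called, and the miR-1283 set was called higher (0.056, 0.0105).

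Leaving out each library in turn gave 1875 to 2492 called genes under miR-99b-5p, 1056 to 1755 under miR-380-3p, 2240 to 3395 under miR-485-3p, 551 to 900 under miR-100-3p, 20 to 36 under miR-1915-3p and 0 to 2 under miR-1283. At 2-fold the ranges were 236 to 335, 144 to 247, 261 to 403, 48 to 92, 2 to 6, and 0 to 0. Seed differences ran from -0.327 to -0.301, -0.109 to -0.028, -0.265 to -0.153, -0.075 to -0.016, -0.062 to -0.029 and -0.001 to 0.081. Counts moved by over 1.5-fold without replicate 3 of miR-380-3p (1056), without its replicate 3 (551, 48 at 2-fold) or control replicate 2 (575) or 5 (597) for miR-100-3p, and without control replicate 2 (24) or 5 (20) or its replicate 3 (20) or 4 (21) for miR-1915-3p, which had 6 at 2-fold without its replicate 2. Under miR-1283 edgeR called 0 without control replicate 2 or 5 or its replicate 1, 3 or 4. The libraries that ended a seed or list call are named in the report. Leaving out 1 library added list calls in 35 cases.

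Of the 30 list calls, which include those of a list not described here, 30 were kept with library-size scaling, 29 without the GC-deviant libraries, 26 with the block, 25 with the GC slope, 21 with a mean CPM of at least 5, 20 without control replicate 5, 19 with the other mimics as reference, 4 with an estimated correlation and 1 with the GC slope and an estimated correlation, the miR-99 and miR-100 targets under miR-99b-5p. With the other mimics as reference the calls lost were markers of other cell types under miR-99b-5p (adjusted p = 0.159), mitosis (0.11), adrenergic (0.282), neuronal (0.147) and miR-99 and miR-100 target (0.802) lists under miR-380-3p, adrenergic genes under miR-485-3p (0.0678) and miR-100-3p (0.903), ribosomal genes under miR-1915-3p (0.185), and mitosis (0.322), interferon (0.279) and cholesterol (0.491) genes under miR-1283.

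Of 368 values of single genes under the naming rule, calls were lost in 27 without the GC-deviant libraries, 21 with the other mimics as reference, 16 with library-size scaling, 11 with the block, 2 with DESeq2 and 0 with the GC slope. With the other mimics as reference MYCN under miR-380-3p (adjusted p = 0.152), IGF1R under miR-99b-5p (0.0505), IFI6 (0.214), NEFM (0.17) and NOTCH2 (0.881) under miR-100-3p, and NEFM (0.0696) and DDC (0.908) under miR-485-3p were not called. Without the GC-deviant libraries CLCN4 (0.0956), PMP22 (0.455) and ASS1 (0.177) under miR-1283 were not called. The report gives calls gained by named genes.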

Other observations

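Tests chosen only after the result was seen were the depth and other-mimic tests for miR-1283, the 4 split tests of miR-1915-3p against the control and the 6 split tests of seed sets after removal of UTR length and GC content, and the genes below were also singled out after their values were seen. The neurofilament gene NEFM was called higher under miR-99b-5p (0.58 ± 0.08), miR-380-3p (0.65 ± 0.08), miR-485-3p (0.42 ± 0.08) and miR-100-3p (0.40 ± 0.08). In all, 11 genes were called higher under these 4 mimics, among them the membrane glycoprotein CD200, the septin SEPT3 and the pseudokinase TRIB1. Another 10 were called lower under all 4, among them DDC and DBH, enzymes of catecholamine synthesis, the granin CHGA, the serotonin receptor HTR3A, the flippase subunit TMEM30A and the receptor NOTCH2. NOTCH2 under miR-100-3p was not called without its replicate 4 (adjusted p = 0.0594). Another 30 genes were called under all 4 with mixed directions. Independent lists of the same sizes would share 0.21, 0.22 and 3 genes, so independence fails for mixed directions as well and is no measure of how far the shared directions exceed chance.

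The same 4 control libraries enter all 4 comparisons. Against the miR-1283 libraries in their place all 84 pairs of a gene and a mimic kept their direction and 65.5% were called. The genes were chosen by their values under these 4 mimics, which favours a kept direction. The calls argue against chance values of the controls as the whole cause for the set, but not for each gene. TRIB1 (0.4 ± 0.1) and PTENP1 (0.54 ± 0.2) lay nearly as high under miR-1283 as under miR-99b-5p (0.43 ± 0.1 and 0.66 ± 0.2). With the GC slope as a covariate 98.8% of the pairs kept their direction and their call, which argues against the GC trend. Under miR-1915-3p, which lowered PABPC1, 11 of the 21 genes had the same direction as under the 4 mimics, and 1 was called, PTGFRN, which fell (-0.25 ± 0.05). Against the miR-1915-3p libraries all 84 pairs kept their direction and 79.8% were called. A response to active mimics, or targets that lie upstream of these genes, stays open and was not tested.

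Genes with a miR-1283 seed site were not lower under miR-1283. Removal of UTR length and GC content left a difference of -0.005 (adjusted p = 0.948), which argues against a fall hidden by these. In simulated libraries of the same depth a fall of 0.1 on the log2 scale gave an adjusted p of 4.27e-14. This argues against depth alone for a fall of that size but not for a smaller one. The simulated genes varied independently, without the GC trend of the real libraries, so the sensitivity in the real libraries was not measured. Over splits of the real libraries the difference of this set reached 0.109, and 0.005 with UTR length and GC content removed. Among the seeds of the other 5 mimics the lowest difference was -0.032, for miR-1915-3p (adjusted p = 0.0522), PABPC1 stood at 1493 ± 60.7 CPM under miR-1283 against 598 ± 76.8 under miR-1915-3p, and 873 to 2931 genes differed from the other 4 mimics, so that libraries holding another of these mimics are unlikely. An inactive or poorly loaded miR-1283 mimic stays open and was not tested.

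Genes with a miR-1915-3p site, a GC-rich heptamer, were lower under miR-1915-3p by -0.046. The same set lay at -0.07 under miR-99b-5p, -0.042 under miR-380-3p, -0.029 under miR-100-3p and -0.032 under miR-1283, none of them called. It lay at 0.015 under miR-485-3p. With UTR length as a term the heptamer had a coefficient of -0.045 under both miR-1915-3p and miR-1283. With GC content as well these were -0.035 and -0.007. With UTR length and GC content removed the difference of the set under miR-1915-3p was -0.027 (adjusted p = 0.173), so a GC trend and a seed effect cannot be told apart by this test. With the GC slope of each library as a covariate the set stayed called (-0.033, adjusted p = 0.0324), but without the GC-deviant libraries it was not (-0.015, adjusted p = 0.433). After removal of UTR length and GC content the real split gave the lowest value of the 35 splits (-0.026 against -0.019), and the heptamer ranked 1 of 16383 with GC content as a term, both chosen after seeing the data. These values go both ways, so the pattern stays open.

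Of the list calls with the preset correlation, 83.3% were kept with the GC slope as a covariate.

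Every comparison was repeated on all 35 splits of its 8 libraries into groups of 4. The real split is 1 of the 35, so 1 of 35 is the smallest share possible. Over many such tests some would reach it by chance. Chance is called excluded only where under 5% of the splits were as large. For the number of called genes, chance can be excluded for miR-99b-5p (real 2940, highest other 1, 1 of 35 splits as large), miR-380-3p (1557 and 45), miR-485-3p (2000 and 1) and miR-100-3p (491 and 98). It cannot be excluded for miR-1915-3p (41 and 480, 2 of 35 splits). At 2-fold the real and highest other numbers were 214 and 1, 169 and 2, 228 and 1, 46 and 10, and 5 and 6 in the order of the report, and chance can be excluded for the first 4 but not for miR-1915-3p (2 of 35). For miR-1283 both real numbers were 0 (highest other 1155 and 44), which every split reaches, so the splits cannot test chance there. These fits use 8 libraries. In them edgeR called 0 genes for miR-1283, against 3 with all 28 libraries, 453 at an unadjusted p under 0.05, 4 by DESeq2 and 3 by limma-voom.

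The splits with many calls point to a structure of the samples. The split with 1155 genes set miR-1283 replicates 1, 2 and 3 and control replicate 1 against the rest, and that with 480 set miR-1915-3p replicates 1 and 3 and control replicates 1 and 2 against the rest. In both, each library of the first set had a lower GC slope than each of the second. The largest component of the residuals held 45.6% of their variance. Across libraries it had an r of 0.997 with the deviation of the GC slope from its group mean. Residuals of libraries from different groups had a mean r of 0.193 within a run of library codes, against -0.094 between runs. The GC slopes of the libraries in the second run of library codes lay on average 1.13 above the mean of their group, against -0.63 for the other runs. With the code runs as a covariate miR-1915-3p had 58 called genes.

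For seed sets, chance can be excluded for miR-99b-5p (-0.313, highest other -0.195, 1 of 35 splits). It cannot be excluded for miR-380-3p (-0.072 and 0.13, 9 of 35), miR-485-3p (-0.225 and -0.231, 2 of 35), miR-100-3p (-0.055 and -0.086, 6 of 35), miR-1915-3p (-0.044 and -0.066, 6 of 35) or miR-1283 (0.025 and 0.109, 21 of 35). With UTR length and GC content removed, a check chosen after seeing the data, the real split gave the largest difference for miR-99b-5p (-0.35 and -0.194). It also did for miR-380-3p (-0.122 and 0.08), miR-485-3p (-0.209 and -0.131) and miR-100-3p (-0.082 and -0.053), each with 1 of 35 splits. Without this removal chance was excluded for miR-99b-5p only. Chance is therefore not called excluded for miR-380-3p, miR-485-3p or miR-100-3p by a check added later. For miR-1915-3p the real split also gave the largest difference (-0.026 and -0.019, 1 of 35). Other checks of that set go the other way, as given above, so chance is not called excluded there. It cannot be excluded for miR-1283 (-0.004 and 0.005, 11 of 35). For the number of lists called, chance cannot be excluded under any mimic: miR-99b-5p (8 and 9, 6 of 35 splits), miR-380-3p (7 and 9, 13 of 35), miR-485-3p (4 and 10, 21 of 35), miR-100-3p (4 and 9, 22 of 35), miR-1915-3p (4 and 11, 20 of 35) and miR-1283 (6 and 12, 12 of 35). The median number of lists called in the other splits was 5, 5, 5, 6, 4 and 5 in the same order. Splits that mix mimic and control libraries thus often call lists at the preset correlation.

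Between mimics, chance can be excluded for 14 of the 15 pairs, each with 1 of 35 splits as large. The real and highest other numbers for miR-99b-5p were 3109 and 15 (miR-380-3p), 3595 and 5 (miR-485-3p), 2687 and 1 (miR-100-3p), 3059 and 1 (miR-1915-3p) and 1968 and 86 (miR-1283). For miR-380-3p they were 2571 and 1 (miR-485-3p), 1618 and 0 (miR-100-3p), 2042 and 398 (miR-1915-3p) and 1330 and 1 (miR-1283). For miR-485-3p they were 2147 and 0 (miR-100-3p), 2350 and 223 (miR-1915-3p) and 1567 and 2 (miR-1283), and for miR-100-3p 1105 and 395 (miR-1915-3p) and 369 and 1 (miR-1283). For miR-1915-3p and miR-1283 chance cannot be excluded (18 and 1995, 3 of 35 splits). The split with 1995 genes set miR-1283 replicates 1, 2 and 3 and miR-1915-3p replicate 1, the 4 libraries of lowest GC slope, against the rest.

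The entry labelled RBM4B carries the identifier of STK26, and 139 tested genes carry the symbol of another gene. Where a symbol and an identifier differ, the identifier was used for the 3′ UTR.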
